A study of Mus musculus with 2 samples.

How the data were processed

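Gene expression was measured in mouse liver with Affymetrix arrays, 1 array for Bglu3 congenic mice and 1 for C57BL/6 apoE-/- control mice. Per the labels, the animals were weaned onto chow at 3 weeks of age, moved to a Western diet at 6 weeks and kept on it for 12 weeks, and biotin-labelled cRNA was made from 8 µg of liver total RNA. The labels do not say how many mice stand behind each array, their sex, whether RNA was pooled, or the time of day at which tissue was taken. The apoE genotype of the congenic mice is not stated in the labels either.

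The deposited table holds 1 linear intensity per probe set and array for 45101 probe sets. How the authors summarized the probes into these intensities, and how they scaled the arrays to each other, is not given in the sources used here. From the values, the median intensity was 19.3 on the congenic array and 19.7 on the control array, and the highest was 14440.3 and 13395. The value 1.00 recurred in 1677 probe sets (3.72%) of the congenic array and 1634 (3.62%) of the control array, so it was treated as a repeated low value. It was not the lowest value, which was 0.47 on the congenic and 0.59 on the control array. The medians of the arrays differed by -0.03 on the log2 scale, below the limit of 0.1 set for rescaling, and the intensities were used as deposited. The 18 hybridisation control probe sets averaged a log2 difference of -0.09, with a range from -0.19 to 0.05.

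Control probe sets (64) were left out of gene counts. Of the other 45037 probe sets, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 had none, and genes were named only from probe sets with 1 symbol. Of these, 34741 matched the gene table of assembly GRCm38.p6, which was used for chromosome membership and gene order alone. No positions are given, because the sources used here do not name the build of the array annotation. Some members of the gene lists (125 of 995) had no probe set with a single symbol here and are not reported here.

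Each of the 18193 genes was represented by its brightest probe set, that with the highest mean over both arrays. A gene counted as expressed when this probe set was at or above the 50th percentile of its array on at least 1 array, which left 12614 genes. Differences are log2(intensity + 5) of the congenic array minus log2(intensity + 5) of the control array, where the pseudocount of 5 is the rounded 20th percentile of all values. Folds are on this scale and understate the difference of dim genes. With 1 array per group there is no spread between animals, no test and no standard error, so genes were counted by a fixed size, 2-fold for single genes and 1.5-fold for members of lists and chromosomes. As a measure of technical disagreement within an array pair, expressed probe sets of the same gene differed with an SD of 0.34 on the log2 scale, from 0.47 among the 1299 dimmest genes with several probe sets to 0.21 among the 1299 brightest.

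The median difference of each of 36 gene lists was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 expressed members was said to stand apart when its median lay outside the central 95% of random lists, as a description of these 2 arrays. The share of genes that differed by 1.5-fold or more was computed in the same way for 20 chromosomes, and within chromosome 1 for windows of 20 Mb with at least 10 expressed genes. Wilson intervals of shares have a level of 95% and cover counting error only. The lists, the size rules and the alternatives were fixed before the data were examined, except for the added lists, tests and alternatives named as such. The named genes are the 12 with the largest positive and the 12 with the largest negative difference among genes that differed by 2-fold or more and whose other expressed probe sets differed in the same direction. To these were added the 2 highest and 2 lowest members of each list, the 5 chromosome 1 genes with the largest difference, and design genes whatever their value, including Apoe and Apoa2.

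Alternatives were median centring, quantile normalization, removal of a loess trend with a span of 0.3, a pseudocount of 20 or none, other filters on expression, other rules for genes with several probe sets, unmatched random lists, and 2-fold in place of 1.5-fold for the chromosome share. The procedure was tested on simulated data in which 200 genes differed by 2 on the log2 scale in either direction, and 12458 expressed genes, 12261 of them unchanged, entered the comparison. It recovered 98% of the changed genes and called 51 of the unchanged ones, with a simulated SD of 0.25 per array. The simulated noise was independent between genes and equal at all levels of expression, and the planted changes exceeded the 2-fold rule. These rates check the procedure and do not carry over to the counts in the data. In the same simulation 7% of 200 lists without a shift stood apart, as did 94% of 50 lists of 20 genes shifted by 0.4, and 60 genes planted on chromosome 1 brought its share to percentile 100. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.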

Results

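Liver RNA of Bglu3 congenic mice was compared with that of C57BL/6 apoE-/- control mice after 12 weeks of a Western diet, with 1 array per group. Bglu3 is a locus for blood glucose on mouse chromosome 1, and a congenic strain carries a donor segment of a chromosome on another strain's background. Both groups are described in the labels as hyperglycemic. The array of the congenic mice carries a title that begins with the chromosome, and the donor strain and the ends of the segment are not given in the sources used here. The intensities of both arrays correlated across all probe sets at 0.978 on the log2 scale, a correlation across probe sets, which are not independent replicates. The ratio of 3' to 5' control probe sets was 1.68 on the congenic and 1.65 on the control array for actin, and 1.25 and 1.23 for Gapdh. There were no replicates, so every difference below describes 2 arrays and has no replicate check.

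The comparison asked which liver genes differ with the congenic segment on this diet. Lists of immune cell, interferon and acute phase genes stood apart on the higher side in the congenic array, and lists of clock, bile acid and drug metabolism genes on the lower side. Ifi202b, an interferon-inducible gene of the p200 family on chromosome 1 that is known to be poorly expressed in C57BL/6 mice, had the largest difference, with an intensity of 237 in the congenic and 1 in the control array (log2 difference 5.33). Hoxa9, a homeobox transcription factor, had the largest difference in the other direction with a pseudocount of 5, at 1.19 against 85.4 (log2 difference -3.87). Of 12614 expressed genes, 241 were higher and 183 lower in the congenic array by 2-fold or more, together 3.36%, while 87.3% lay within 1.5-fold and the median difference was 0.04.

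The 12 genes with the largest positive difference included myeloid granule genes, and the order of the 12 depends on the pseudocount of 5. Camp, the cathelicidin antimicrobial peptide, had an intensity of 151 against 6.35 (log2 difference 3.78), Prtn3, a serine protease of neutrophil granules, 194 against 16.6 (3.20), and Mpo, myeloperoxidase, 81.2 against 9.28 (2.59). Genes of antibody-producing cells were of similar size. The kappa variable segment Igkv8-30 stood at 557 against 47.3 (log2 difference 3.42), Jchain, which joins polymeric immunoglobulins, at 391 against 49.4 (2.87), and the heavy chain gene Ighg3 at 35.6 against 1 (2.76). Cxcl13, a chemokine that attracts B cells, had a log2 difference of 3.03 with 643 against 74.3, and both of its probe sets lay between 2.95 and 3.03. Prg2, the major basic protein of eosinophils, differed by 2.74 from a control value of 1, and Orm2, an acute phase glycoprotein secreted by hepatocytes, by 2.60 at a high level, with 5520.0 against 904. The matricellular protein gene Ccn1 (log2 difference 2.83) and the helicase gene Ighmbp2 (2.65) completed these 12, and their probe sets spread from 0.80 to 2.98 and from 0.28 to 2.65.

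The order of the 12 genes with the largest negative difference also depends on the pseudocount. Maff, a small Maf transcription factor, had a log2 difference of -2.39 and an intensity of 22.6 against 139.7. Foxq1, a forkhead transcription factor, differed by -2.30 with 60.7 against 318. Lpin1, a phosphatidate phosphatase of triglyceride synthesis that also acts as a coactivator, was the brightest of them, at 498 against 2078 (log2 difference -2.05), and its probe sets lay between -2.35 and -2.05. Nkd2, an antagonist of Wnt signalling, differed by -2.22, the RNA helicase gene Ddx19b by -2.15, the cytochrome P450 gene Cyp3a16 by -2.16 and the kinesin gene Kif18b by -2.08. Prf1, the perforin of cytotoxic lymphocytes, stood at 7.5 against 57.2 (log2 difference -2.32), and the kinase gene Matk at 7.99 against 60.2 (-2.33). Zgrf1, a helicase of DNA repair, and S100g, a calcium-binding protein, were at the repeated low value of 1 in the congenic array, with log2 differences of -2.35 and -2.33.

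Of the 424 genes past 2-fold, 89 had at least 2 expressed probe sets, and in 68 of these (76.4%) all probe sets differed in the same direction, compared with 52.3% of the 5195 expressed genes with several probe sets. The 424 genes were picked for a large difference in their brightest probe set, so more agreement is built into this comparison. Probe sets of a gene also read the same 2 arrays, so their agreement says nothing about other animals. The size of a difference from a value near 1 depends on the pseudocount, and Ifi202b differed by 3.61 with a pseudocount of 20 and by 7.89 with none.

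**Figure D1:**
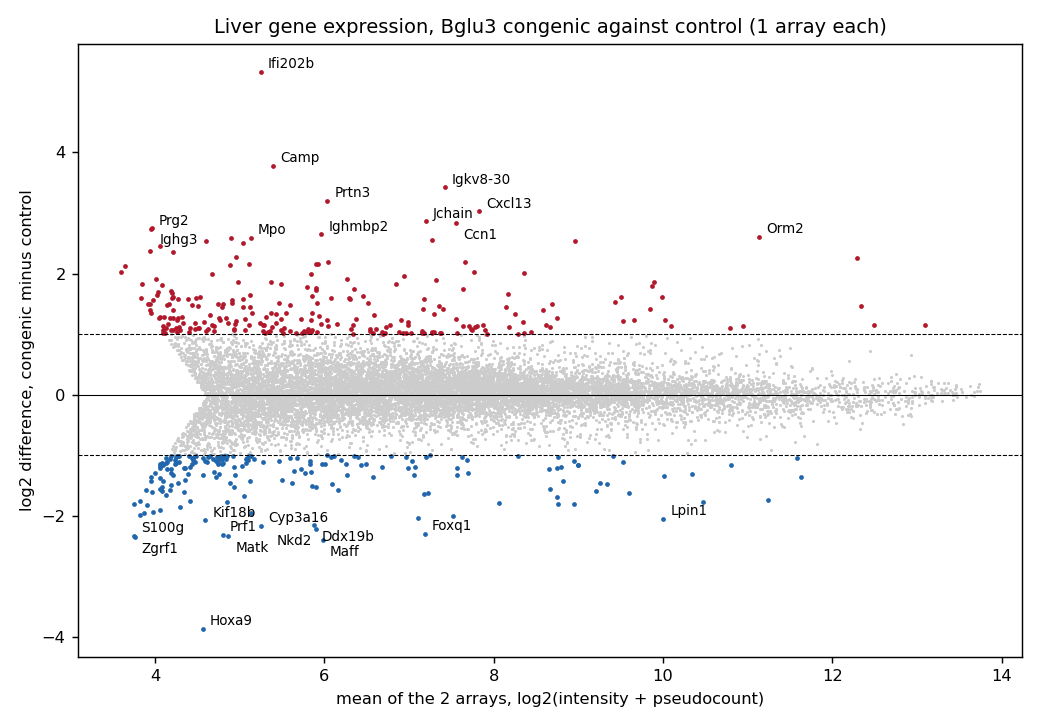
Each point is an expressed gene, with the mean log2(intensity + 5) of both arrays on the x axis and the log2 difference, congenic minus control, on the y axis. Red and blue points are the 241 genes higher and the 183 genes lower by 2-fold or more (dashed lines), and the 12 genes with the largest difference each way are named.

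Markers of several immune cell types were higher in the congenic array. Of 36 gene lists fixed in advance, 34 had enough expressed members to be ranked, and 15 had a median outside the central 95% of random lists, 7 above and 8 below. Lists of unrelated genes would give 1.7. Genes of a list can vary together and some lists share members, so 1.7 is likely too low a mark for these lists. Neutrophil markers had the highest median of all lists, 1.41, above all 10000 random lists, with 9 of 13 expressed members higher by 1.5-fold or more and none lower. Only 9 of the 13 were expressed on the control array, and the median was 0.92 when expression was required on both arrays and 2.08 with the 75th percentile as the filter. Camp and Prtn3 led this list, while Mmp9, a gelatinase, and Csf3r, the receptor for granulocyte colony-stimulating factor, had log2 differences of -0.31 and 0.01. T, B and NK cell markers had a median of 0.70, with 11 of 17 members higher and 0 lower, led by Jchain and Ighm, the mu heavy chain, at 429 against 89.8 (log2 difference 2.19). The probe sets of Ighm ranged from -0.09 to 2.66, and Il7r, the receptor for interleukin 7, differed by -0.29. Macrophage and Kupffer cell markers had a median of 0.60, with 15 of 29 members higher and 1 lower. Marco, a scavenger receptor of macrophages encoded on chromosome 1, stood at 1798 against 494 (log2 difference 1.85) and Timd4, a marker of resident Kupffer cells, at 506 against 157 (1.66). Gpnmb, a gene of lipid-laden macrophages, went the other way with 279 against 649 (-1.20), and the chemokine Ccl2 differed by 0.11.

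Other resident and contaminating cell types differed less. Liver endothelial markers had a median of 0.12 (percentile 83.8), with 0 members higher and 1 lower of 20, and their extremes were Cdh5, the endothelial cadherin, at 0.53 and Lyve1, a hyaluronan receptor of sinusoids, at -0.64. Stellate cell and fibrosis markers had a median of 0.14 (percentile 94.7), with 7 of 29 higher and 1 lower, among them Rgs5 at 1.14 and the collagen gene Col1a1 at 1.12, and they stood apart under 5 of 11 alternatives. Hepatocyte markers had a median of 0.03, and all 17 expressed members lay within 1.5-fold, including albumin (Alb, 0.13) and Hnf4a, a hepatocyte transcription factor (-0.26). Alb stood at 14121 against 12910, near the highest intensities of the arrays (14440.3 and 13395), where a difference may be compressed. Cholangiocyte markers had a median of 0.08 with none of 8 past 1.5-fold, and erythroid markers -0.09 with 1 of 9 higher (Klf1, 0.88) and 1 lower (Car1, -0.66). Pancreatic acinar markers had a median of 0.14 with 3 of 8 higher, led by the trypsinogen-like 2210010C04Rik at 67.8 against 11.3. Skeletal muscle markers had a median of -0.36 over 5 members, inside the range of matched random lists but outside that of unmatched ones (percentile 1.22). Adipocyte and kidney markers had 3 expressed members each, with medians of 0.14 and -0.14, and were not ranked.

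Acute phase, interferon and antigen presentation genes stood apart on the same side as the immune cell markers. Interferon-stimulated genes had a median of 0.32, with 9 of 36 members higher and 1 lower. Zbp1, a sensor of nucleic acids, and Oasl2, of the oligoadenylate synthetase family, each differed by 1.01, while the chemokine Cxcl10 and the deconjugating enzyme Usp18 differed by -0.60 and -0.57. MHC and antigen presentation genes had a median of 0.54, with 6 of 12 higher and none lower. The class II genes H2-DMa (log2 difference 0.97) and Cd74, the invariant chain (0.68), were its highest members, whereas the class I genes H2-K1 and H2-Q10 differed by 0.04 and -0.12. Acute phase proteins had a median of 0.19 at percentile 99.99, with 7 of 25 higher and 1 lower, and lay at percentile 97.4 of random lists not matched on level, inside their central 95%. Saa2, a serum amyloid A gene, followed Orm2 at 10938.5 against 2281 (log2 difference 2.26), while Saa4, the constitutive family member, differed by -0.82. Complement and coagulation genes had a median of 0.06 (percentile 96.3), with 5 of 34 higher and none lower, including C6 (1.26) and C1qb, which macrophages make (0.78). The p200 family list had a median of 0.18 over 5 expressed members, inside the random range. By their brightest probe sets, its members other than Ifi202b ranged from -0.41 for Ifi204 to 0.53 for the DNA sensor Aim2. Other probe sets spread further, since Ifi209, whose brightest probe set gave the median, had another at -2.38, and Mndal had another at 0.89. Probe sets of serum amyloid, orosomucoid, immunoglobulin, class I and p200 genes can bind transcripts of close relatives, so values of single members of these families are uncertain.

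**Figure D2:**
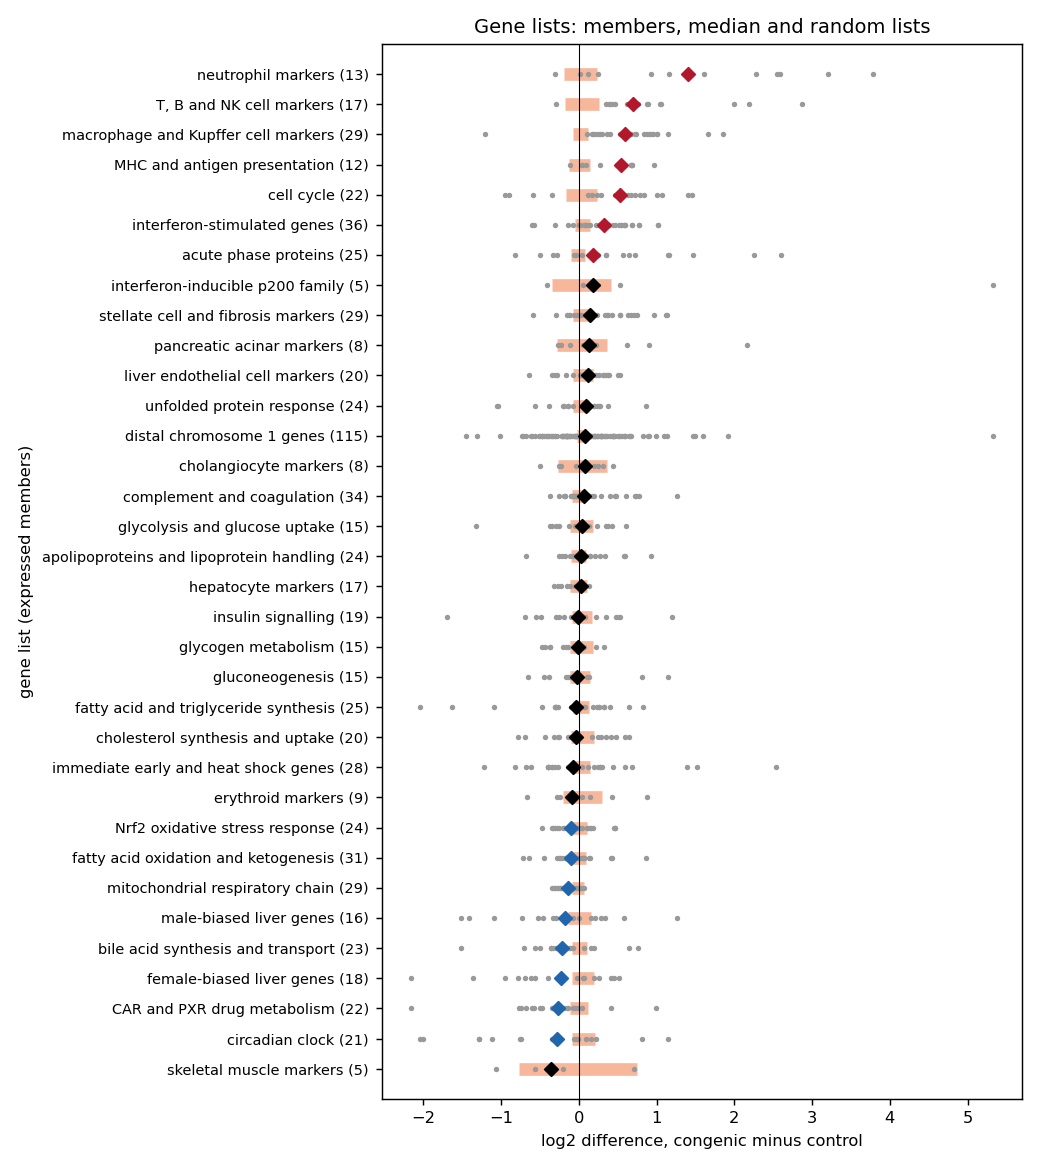
Each row is a gene list, with the number of expressed members in brackets, and the x axis is the log2 difference, congenic minus control. Grey points are members, diamonds are list medians (red or blue where they lie outside the central 95% of 10000 random lists matched on level, which the orange bar spans), and 15 of 34 medians lie outside.

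Lists for glucose handling did not stand apart, although single members differed. Gluconeogenesis had a median of -0.03 over 15 members, with 2 higher and 1 lower. G6pc, the catalytic subunit of glucose-6-phosphatase, which releases glucose from the liver, stood at 2923 against 1321 (log2 difference 1.14) and the aminotransferase gene Got1 at 2735 against 1549 (0.82). Foxo1, a transcription factor restrained by insulin, differed by -0.65, with probe sets from -0.79 to 0.16, and Slc37a4, the glucose-6-phosphate transporter, by -0.45. Insulin signalling had a median of -0.01 over 19 members, and its extremes were components of the same cascade. Irs1, an insulin receptor substrate that lies on chromosome 1, differed by 1.20 (488 against 210.0), and Pik3r1, the regulatory subunit of phosphoinositide kinase, by -1.70 (234 against 771), with a range over its probe sets from -1.70 to -0.47. Socs1, a suppressor of cytokine signalling, differed by -0.69 and the adaptor gene Grb10 by 0.53. Glycolysis and glucose uptake had a median of 0.04 over 15 members, with Pfkfb3, which makes an activator of phosphofructokinase, at -1.32, the fructokinase gene Khk at -0.37, Hk2 at 0.61 and Pkm at 0.43. Glycogen metabolism had a median of -0.01 and no member of 15 past 1.5-fold, between Ppp1r3c at -0.47 (another probe set at 0.33) and the glycogenin gene Gyg at 0.32.

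Lipid genes were mixed. Fatty acid and triglyceride synthesis had a median of -0.03 over 25 members, with 2 higher and 3 lower. Besides Lpin1, Thrsp, a lipogenic nuclear protein, was lower at 434 against 1356 (log2 difference -1.63, with probe sets from -1.63 to 0.12), while Acacb, an acetyl-CoA carboxylase, and the elongase gene Elovl6 differed by 0.83 and 0.65. Cholesterol synthesis and uptake had a median of -0.04 over 20 members, between Stard4, a sterol carrier (-0.78), and Hsd17b7 (0.64), with Insig1, which retains the sterol sensor in the endoplasmic reticulum, at -0.69 and Mvd at 0.59. Apolipoproteins and lipoprotein handling had a median of 0.03 over 24 members. Apoe, the gene disrupted in the control strain, had an intensity of 229 in the congenic and 118 in the control array (log2 difference 0.93), and where its probe set lies relative to the disrupted part is not known here, so this value does not check the genotype. Apoa2, an apolipoprotein of high-density lipoprotein encoded on chromosome 1, stood at 13319 against 12041 (0.15), Lpl, the lipoprotein lipase, differed by 0.60, Angptl8, an inhibitor of that enzyme, by -0.68 and Apod by -0.26.

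Fatty acid oxidation and ketogenesis stood apart on the lower side with a small median of -0.10 (percentile 0.6) over 31 members, of which 21 were lower at any size and 2 by 1.5-fold or more. With only probe sets whose name ends in a plain _at, its median was -0.10 and lay inside the central 95% of random lists. Ppara, the nuclear receptor that governs this pathway, differed by -0.63 (882 against 1373) and Decr2, a peroxisomal reductase, by -0.71, while the Ppara target Fgf21 differed by 0.87 and Cpt1a, the mitochondrial gatekeeper enzyme, by 0.42. The mitochondrial respiratory chain had a median of -0.14 (percentile 0.15), and 27 of its 29 members were lower, none by 1.5-fold. Uqcrc1 and Sdha, of complexes of the chain, differed by -0.34 and -0.32, and Uqcrb and Ndufa2 by 0.03 and 0.07. The Nrf2 oxidative stress response had a median of -0.09 (percentile 1.27) and no member of 24 past 1.5-fold, and after quantile normalization (median -0.09) it lay inside the central 95%, as it did among random lists not matched on level (percentile 2.83). Its members lay between the glutathione transferase gene Gsta2 at -0.47 and Nfe2l2, which encodes Nrf2 itself, at 0.47. Gclc differed by -0.34 and Pgd by 0.46.

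Genes of bile acid and drug metabolism were lower as groups. Bile acid synthesis and transport had a median of -0.22, below all 10000 random lists, with 18 of 23 members lower at any size, though only 2 by 1.5-fold or more and 2 higher by that much. Slco1a1, a bile acid and steroid uptake transporter, stood at 29.3 against 92.7 (log2 difference -1.51) and the oxysterol hydroxylase gene Cyp39a1 differed by -0.70. In contrast, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.64 (1818 against 1162) and Cyp8b1, which sets the share of cholic acid, by 0.77 (2353 against 1382). The CAR and PXR drug metabolism list, which also holds these receptors' own genes and the Cyp1a genes that the aryl hydrocarbon receptor governs, had a median of -0.27 (percentile 0.01), with 5 of 22 lower and 1 higher. Besides Cyp3a16, Cyp1a1 was among the 5 at 10.2 against 20.9 (log2 difference -0.77), while Cyp2b10, a classical CAR target, differed by 0.99 and the estrogen sulfotransferase gene Sult1e1 by 0.41. Female-biased liver genes had a median of -0.23 (percentile 0.03), with 6 of 18 lower and 0 higher. Sult2a2, a steroid sulfotransferase, stood at 1973 against 5054 (log2 difference -1.35), and Atp6v0d2 and Cyp17a1 differed by 0.52 and 0.45. Male-biased genes had a median of -0.18 (percentile 0.56), with 4 of 16 lower and 1 higher, C6. Among the lower ones was Cyp4a12a at -1.42, dim at 7.49 against 28.3, while Serpina12 differed by 0.58. This last list no longer stood apart without a filter on expression (-0.07), with the 75th percentile as the filter (-0.0015) and with expression required on both arrays (-0.04). Cyp3a, Sult2a and related families have near-identical members, and the signal of a probe set can come from more than 1 of them.

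Circadian clock genes had a median of -0.28 (percentile 0.01), with 7 of 21 lower by 1.5-fold or more and 2 higher. The 2 higher genes were Arntl, the core activator of the clock also called Bmal1, at 157 against 68.6 (log2 difference 1.14), and its partner gene Npas2, which lies on chromosome 1, at 37.9 against 19.6 (0.81). Usp2, a deubiquitinase under clock control, stood at 86.7 against 363 (-2.0), and Wee1, a clock-controlled cell cycle kinase, at 63.0 against 275 (-2.04), with its probe sets between -2.04 and -0.01. Immediate early and heat shock genes went both ways, with 5 of 28 higher and 4 lower and a median of -0.07 (percentile 2.66). Fos stood at 1195 against 202 (log2 difference 2.54) and Jun at 1163 against 402 (1.52), while the heat shock gene Hspa1b stood at 260 against 613 (-1.22) and Fosl2 differed by -0.82, with its other probe set at 0.65. The unfolded protein response had a median of 0.09 over 24 members, although Herpud1, of degradation at the endoplasmic reticulum, stood at 2129 against 4422 (log2 difference -1.05) and Chac1 differed by -1.04. Asns, the asparagine synthetase gene, and the chaperone gene Calr differed by 0.86 and 0.37.

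Cell cycle genes had a median of 0.53, above all random lists, with 9 of 22 higher and 3 lower, and 17 of the 22 were expressed on the control array. Mki67, a marker of cycling cells, stood at 32.8 against 8.71 (log2 difference 1.46) and the cyclin gene Ccnb2 at 25.1 against 6.38 (1.40), both dim. Cdkn1a, the inhibitor of cyclin-dependent kinases known as p21, was lower at 579.7 against 1126 (-0.95), as was Rrm2, of ribonucleotide reductase, at 127 against 242 (-0.90). When only genes at or above the 75th percentile on 1 array were kept, 5 members remained and their median was -0.34, of the opposite sign.

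Chromosome 1, which carries the Bglu3 locus, had the highest share of differing genes among 20 chromosomes. Of its 732 expressed genes, 118 (16.1%, Wilson interval 13.6% to 19.0%) differed by 1.5-fold or more, 72 higher and 46 lower, compared with 12.5% of 11830 genes on the other chromosomes. This share lay at percentile 99.59 of random gene sets matched on level, whose median was 13.1%. The 5 chromosome 1 genes with the largest difference were Ifi202b, the potassium channel genes Kcnt2 (137 against 25.9, log2 difference 2.19) and Kcnj10 (145 against 34.8, 1.91), Marco, and Ifi213, another p200 gene (5.34 against 32.2, -1.85). By gene order in assembly GRCm38.p6, the highest shares among 10 windows of 20 Mb were in the distal part of the chromosome. The window from Kcnt2 to Cop1 had 11 of 48 genes differing (22.9%, 13.3% to 36.5%), among them Ivns1abp at -1.46 (probe sets from -1.60 to 0.07) and Rgs16, a regulator of G protein signalling, at 818 against 2032 (log2 difference -1.31). The next window, up to Cdc42bpa, had 26 of 132 (19.7%, 13.8% to 27.3%), 18 higher and 8 lower, and holds Ifi202b, Kcnj10, Ifi213 and Apoa2. The list of distal chromosome 1 genes fixed in advance had a median of 0.08 over 115 members, inside the central 95% of random lists. A signed median does not measure the share of genes that differ either way. By 1.5-fold or more, 17 members were higher and 8 lower, with 90 between, and this share was not ranked among random sets.

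Chromosome 7 also lay outside the central 95% on the upper side, with 146 of 951 genes (15.4%, percentile 98.3). On the lower side, chromosome 11 lay outside this range, with 111 of 1029 genes (10.8%, percentile 1.02). The share on chromosome 1 lay inside it with a pseudocount of 20 (percentile 95.4) and with the 75th percentile as the filter (percentile 96.5).

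**Figure D3:**
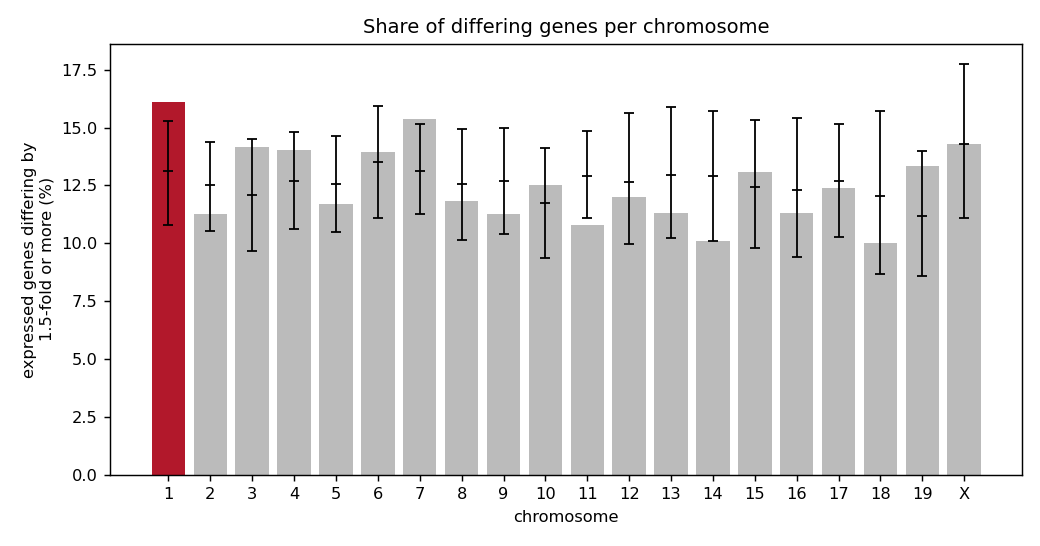
Bars give the percent of expressed genes on each chromosome that differed by 1.5-fold or more, and whiskers the median and central 95% of 10000 random gene sets of the same size matched on level. Chromosome 1 (red) has the tallest bar, 16.1%, above its whisker.

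**Figure D4:**
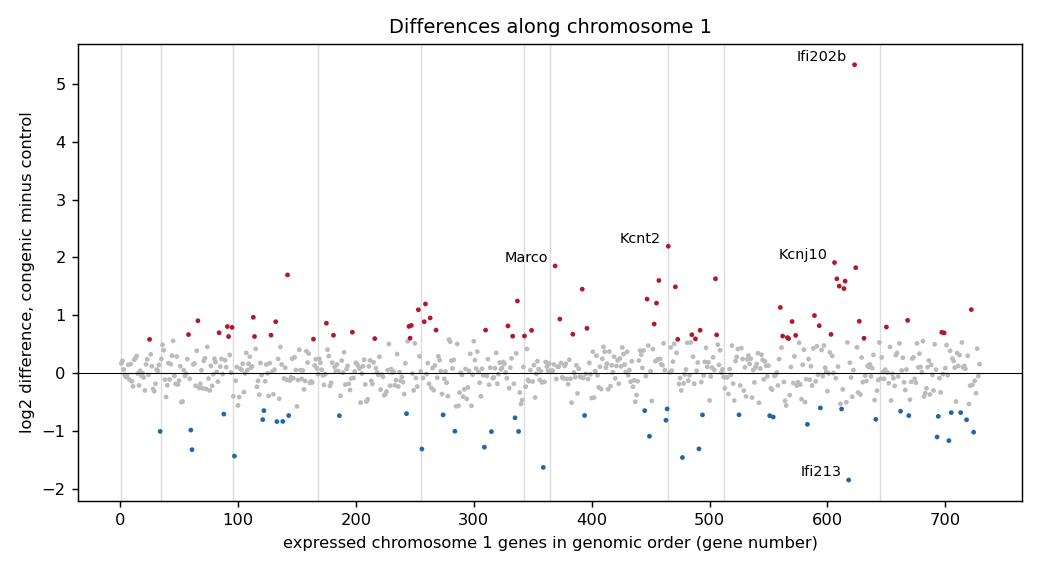
Expressed genes of chromosome 1 are placed in genomic order (x axis, gene number) with the log2 difference, congenic minus control, on the y axis. Red and blue points differ by 1.5-fold or more, grey lines separate windows of 20 Mb, and the 5 genes with the largest difference are named.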

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

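The tests of hepatocyte share, blood, lymphoid or marrow tissue, time of day, an effect of the donor segment on the clock and probe sequence were chosen only after the result was seen. The test without immune list members was added after the data were seen, with its bound written before its own value was computed. Probe sets without a single gene name lay outside the gene comparison and were looked at because they also carried signal. Of 2975 such expressed probe sets, 112 were 2-fold or more higher in the congenic array and 104 lower, so 3.76% were higher and 3.50% lower, compared with 1.91% and 1.45% of named genes. The named genes are each represented by their brightest probe set and the unnamed probe sets are all counted, so these shares are not of like features.

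Immune cell markers were higher in the congenic array, with medians of 0.60 for 29 macrophage genes, all of which were also expressed on the control array, and 0.70 for 17 lymphocyte genes, of which 16 were. A smaller share of hepatocyte RNA would raise all other cell types alike. The macrophage median exceeded the endothelial one by 0.48 (bootstrap interval over genes 0.22 to 0.78). More blood in the sample would raise erythroid markers too, and the lymphocyte median exceeded the erythroid one by 0.79 (0.32 to 1.14). These medians were known when the lists were paired, and the intervals cover the choice of genes, not animals, so neither cause is excluded. Only 9 erythroid members were expressed, and the globin gene Hba-a2 was dim, at 23 against 28.9, so blood was barely measured. After a trend of difference on level was removed, the macrophage median was 0.57 and still above all random lists. The random lists were already matched on level, so this rank could hardly change. The median itself moved only from 0.60 to 0.57, so a trend on level shared by all genes accounts for little of it. Infiltration in these livers and a piece of lymphoid or marrow tissue in the sample cannot be told apart, because the erythroid median of -0.093 bears only on marrow or spleen with red cell precursors, and there is 1 array per group. Cd5l, a macrophage gene with a bright probe set, stood at 7404 against 6501, and S100a8, a neutrophil gene, at 1769 against 577.

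Clock genes stood apart as a list, with members going both ways. The median of 3 genes that peak early in the day (Arntl, Npas2 and Clock, all higher, median 0.81) exceeded that of 11 genes that peak later (all lower, median -0.75) by 1.56 (bootstrap interval 0.44 to 2.42), but these groups were formed after the values were seen, leave out 7 of the 21 members and largely restate them, so tissue taken at different times of day remains open. After the trend on level was removed, the clock list median was -0.31 and lay below all random lists, which were already matched on level. The median did not shrink from its value of -0.28, so a trend on level shared by all genes does not account for it. An effect of the donor segment on the clock (list median -0.28) and the time of tissue collection cannot be told apart with 1 array per strain, and the labels give no time of day. Clock itself differed by 0.09, and Per1 and Cry1, in neither group, by -0.07 and -0.03.

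The share of differing genes was higher on chromosome 1 (16.1%) than on any of the other chromosomes. In 8.6% of 2000 reassignments of differences among genes of like level some chromosome reached a percentile as high. This rate is for any chromosome, whereas chromosome 1 was singled out by the design, since it carries the Bglu3 locus. For chromosome 1 alone, the share lay at percentile 99.59 of random gene sets matched on level. With a larger pseudocount (percentile 95.4) or the 75th percentile as the filter (96.5), it lay inside the central 95%. Under the other alternatives it lay above this range. Chance is therefore not excluded. Donor sequence under probes made to the C57BL/6 sequence would make signals lower in the congenic array, and the share of lower genes among the differing ones was 39.0% on chromosome 1 and 41.4% elsewhere, a difference of -2.43 percentage points (-11.5 to 6.66) that does not decide it. Without members of the immune lists the percentile was 99.79, but only 9 genes, 3 of them differing, were left out, too few for the share to move, and the bound set for this test was therefore wrong. An effect of the donor segment on its own genes remains open and untested, since the ends of the segment are not given in the sources used here.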

How the results depend on the processing

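The alternatives without genes at the repeated low value of 1, with agreeing probe sets only and without immune list members were chosen after seeing the data, the last with its bound written before its own value was computed. The number of lists that stood apart was 14 to 16 in the 12 alternatives in which lists were ranked (15 as reported), and 13 to 15 of them were shared with the reported ones. Against 241 genes higher and 183 lower by 2-fold, a pseudocount of 20 gave 105 and 65, no filter on expression 383 and 365, the 75th percentile as the filter 103 and 60, expression required on both arrays 141 and 82, and only genes with 2 or more agreeing probe sets 36 and 32, where the filters and the last alternative change the number of genes counted. Against a chromosome 1 share of 16.1%, these first 4 settings gave 8.74%, 20.2%, 10.6% and 11.1%, and 2-fold in place of 1.5-fold gave 5.19%; for the pseudocount the cause was not tested. The other alternatives, those of scaling included, left these counts within 1.5 times and the share inside its interval. The cell cycle median was reversed to -0.34 with the 75th percentile as the filter, which left 5 members. Of the other list medians under 11 alternatives, 347 kept their side of the random range, 5 lost their place outside it and 11 gained one, and with unmatched random lists acute phase proteins (percentile 97.4) and the Nrf2 response (2.83) lost theirs and skeletal muscle (1.22) gained one. None of the 59 named genes past 2-fold had the opposite sign under any of 11 alternatives, while 5 of the smaller ones had in at least 1, and 40 of all 158 named genes moved by more than the SD of 0.34 between probe sets of a gene in at least 1. A pseudocount or a filter on expression cannot change the sign of a probe set, so several of these alternatives could hardly reverse a gene. Dim signal limits the counts, since the SD between probe sets was 0.47 among the 1299 dimmest genes with several probe sets (median intensity 37.8) and 0.21 among the 1299 brightest (468), and 7 of the genes past 2-fold were at the repeated low value on 1 array. No paired analysis was possible because each group has 1 array, and leaving out an array was not possible for the same reason.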

Other observations

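The lists in this part were made only after the result was seen and hold genes that prompted them, so their medians describe those genes and no rank among random lists is given. Granule genes that immature granulocytes transcribe in bone marrow had a median log2 difference of 2.15, with 8 of 10 expressed members higher by 1.5-fold or more and none lower. Of the 10, 6 were expressed on the control array, the others on the congenic array alone, and 7 are also members of lists fixed in advance. Besides Camp, Prtn3 and Mpo they included Ngp at 369 against 58.7 (log2 difference 2.55), Ltf, lactoferrin, at 63.2 against 9.10 (2.27) and Chil3 at 433 against 103 (2.02), while Elane and Ms4a3, also genes of early granulocytes, differed by 0.24 and -0.13. Genes assigned to mature neutrophils, among them Mmp9 and Csf3r, whose values were already known, had a median of -0.16, with 1 of 12 higher (G0s2, also a gene of hepatocyte lipid metabolism, 1.10) and 3 lower, among them Hdc (-1.06) and Clec4d (-0.92). This list leaves out S100a8, a neutrophil gene that was higher in the congenic array, so a contrast with the granule genes depends on the choice of members. Immunoglobulin and plasma cell genes had a median of 1.30, with 8 of 14 higher and 1 lower, and 10 of the 14 were expressed on the control array. Pou2af1, a B cell coactivator, stood at 55.3 against 11.6 (log2 difference 1.87) and Cd79b, of the B cell receptor, at 109.8 against 23.9 (1.99), while the plasma cell regulators Prdm1 and Xbp1 differed by 0.23 and -0.20. Of the eosinophil genes only Prg2 (2.74) and Prg3 (-0.30) were expressed.

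Liver genes that respond to glucocorticoids had a median of -0.32, with 8 of 27 lower by 1.5-fold or more and 3 higher, and 13 of the 27, such as Pik3r1 and Cdkn1a, are also members of lists fixed in advance. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 261 against 920.2 (log2 difference -1.80), Zbtb16 at 337 against 1020 (-1.58), Arrdc2 at 30.1 against 96.1 (-1.53) and Tsc22d3, which encodes the leucine zipper protein GILZ, at 962 against 1703 (-0.82). Tat, Pck1 and Sgk1, other genes that respond to these hormones, differed by 0.00, -0.02 and 0.10. Housekeeping genes had a median of 0.08, with 1 of 16 lower (Tbp, -0.73).

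The sex of the mice is not given in the labels. The brightest Xist probe set stood at 2132 on the congenic and 1711 on the control array, and the brightest probe set of the Y-linked gene Uty at 19.1 and 34.8. The other Uty probe sets and all those of the Y-linked genes Eif2s3y and Kdm5d lay below the expression limits of 19.3 and 19.7. Those of Eif2s3y reached at most 14.9 and those of Kdm5d 16.4, both on the control array. Bright Xist with dim Y-linked genes argues against RNA from males alone on either array. Across 139 windows of the genome, the highest share of differing genes was 13 of 35 (37.1%) in the window from Mup10 to Ptprd on chromosome 4, which holds a family of near-identical major urinary protein genes, and the window from Kcnt2 to Cop1 on chromosome 1 was the sixth.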
